A study of Mus musculus with 24 samples.

How the data were processed

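The values analysed were the deposited log2 expression values of 24 whole-transcript arrays, used as they are. Per the submitters' processing notes the authors obtained them by RMA; the RMA version and the log base are not given in the sources used here, and log2 was taken from the range of 0.87 to 13.6. Array medians lay between 4.57 and 4.65. Per the labels' protocols, livers were snap frozen, total RNA was isolated with an RNeasy micro kit, whole transcript cDNA was made with the Ambion WT expression kit, and the product was labelled with biotin. Per the labels all mice were male C57BL/6 animals on chow, 9 to 12 weeks old, and each array held 1 mouse.

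The table held 35556 probe sets. Of these 21218 mapped to 1 gene symbol and were used, 1881 mapped to several symbols and 12457 were not listed in the probe table, and both of the latter kinds entered only the alternative with all probe sets. Current symbols were taken by gene number for 21185 probe sets from a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. Where several probe sets carried 1 symbol the one with the highest mean over all arrays was kept, which left 18820 genes. No detection calls were used here, so levels near the lower end of the scale may be background. Families of close copies, such as the Cyp2b and Mup genes, may share signal between their probe sets.

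A 4-group means model was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with 20 residual and 4.46 prior degrees of freedom. The contrasts were OCA against vehicle in wild-type liver, the same in knockout liver, knockout against wild type under vehicle, and the difference of the OCA effects. P-values were adjusted by Benjamini-Hochberg over 18820 genes and a gene was called at adjusted p < 0.05. The 34 gene lists were tested with camera using an estimated correlation, adjusted over the lists within a contrast, and members were counted over all genes and over the list alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Groups are given as mean ± SD and changes as log2 change ± SE.

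The groups, the model, the gene lists, the rule for naming genes and 14 alternative settings were fixed before the data were examined. The named-gene rule took Nr1h4, Nr0b2, Abcb11, Slc51b, Cyp7a1 and Cyp8b1 always. It added the called genes with the largest absolute change (12 each way for OCA in wild-type liver, 10 each way for knockout, 5 each way for the other 2 contrasts) and up to 4 members with the smallest p per list, and skipped predicted genes. Genes outside this rule are said in the text to have been picked after their values were seen; the genes of wild-type vehicle replicate 6, of the region next to Nr1h4, of the macrophage and hepatocyte lists and of the sex chromosomes belong to these.

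The alternatives were centring on each array's median, quantile normalization, filters at a mean signal of 20 and at the median gene, trend with robust eBayes, array weights, only the groups compared, the array code number as a block, 1 array code number alone, the array code letter as a block, leaving out the 4 arrays whose names end in _2, the replicate number as a block, all probe sets, and leaving out each array in turn. Camera was also run with a preset correlation of 0.01, with the number block and with the replicate block. Chosen after the data were seen were centring on the named genes, the number block without wild-type vehicle replicate 6, the lists and the overlap without that array, a list of lipid-associated macrophage genes and a list of major hepatocyte transcripts. The meaning of the array code number and of the ending _2 is not given in the sources used here.

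The fits were tested on simulated data with 200 changed genes. At a log2 change of 0.5, 1 and 2, recovery was 71.5%, 99.5% and 100% for OCA in wild-type liver, 74%, 99% and 100% for OCA in knockout liver, 75.5%, 98.5% and 100% for knockout, and 39.5%, 92.5% and 99.5% for the difference between genotypes. Recovery after adjustment depends on how many genes change, and the simulated noise was normal with no array that stands apart. These percentages therefore do not give the recovery in the real comparisons, where the number of changed genes is not known. Over 100 simulations camera found a list of 20 genes shifted by 0.5 in 100% and called an unshifted correlated list in 2% with the estimated correlation and in 42% with the preset one. The shifted list had independent members, the unshifted list had members correlated at 0.5, and both were scored at unadjusted p < 0.05. The 100% therefore does not give the recovery for the real lists, whose members may be correlated and which were adjusted over 34 lists. Nor does the 42% give the rate of false calls for real lists, which may be less or more correlated. For each comparison between groups 100 splits of the same arrays were drawn, and shared vehicle arrays were allowed for in the overlap by simulating unchanged groups and by splitting the vehicle arrays 3 and 3. The test for single arrays far from their group was run only on the 39 genes named by the first parts of the rule or called for OCA.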

Results

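Livers of 24 male mice were measured, 1 array per mouse, in 4 groups of 6: wild-type and FXR-knockout mice given vehicle or obeticholic acid (OCA), a semi-synthetic agonist of the bile acid receptor FXR. Per the labels, OCA was given at 10 mg/kg/day by daily oral gavage for 7 days and the vehicle was 1% methyl cellulose. The deposited log2 values covered 18820 named genes, and arrays correlated with each other at 0.9709 to 0.9911. The first principal component held 54.9% of the variance and separated all wild-type arrays (−31.9 to −23.9) from all knockout arrays (25.8 to 30.6). The next component (7.9%) set wild-type vehicle replicate 6 at −48.1 apart from the other 23 arrays (−6.7 to 9.9). In that array 532 genes lay over 2-fold from the mean of the other 5 wild-type vehicle arrays, against 2 to 90 genes in any other array compared with its own group.

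Nr1h4, the gene that encodes FXR, gave nearly the same signal in both genotypes. The wild-type vehicle arrays read 10.19, 10.05, 10.11, 10.30, 9.96 and 10.23, and the wild-type OCA arrays 10.28, 10.00, 10.15, 9.85, 9.96 and 10.15. The knockout vehicle arrays read 9.88, 9.92, 9.90, 9.89, 10.13 and 10.10, and the knockout OCA arrays 9.80, 9.86, 10.05, 9.93, 9.94 and 9.95. Group means ± SD were 10.14 ± 0.12, 10.07 ± 0.16, 9.97 ± 0.11 and 9.92 ± 0.09. The knockout difference of −0.17 ± 0.07 (SE) did not pass (limma, Benjamini-Hochberg adjusted p = 0.0935, n = 6), and without wild-type vehicle replicate 5 it was −0.20 with adjusted p = 0.0444. A probe set outside the deleted part of a gene checks nothing about a knockout, and the position of these probes is not given in the sources used here. Of genes induced by the receptor and always named, Nr0b2, the nuclear repressor SHP, reached at most 4.82 in any knockout array and at least 5.87 in any wild-type array. Slc51b, a subunit of the basolateral bile acid exporter, reached at most 3.97 in knockout and at least 4.42 in wild-type arrays.

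OCA raised the FXR target genes Nr0b2 and Slc51b and lowered the bile acid hydroxylase gene Cyp8b1 in wild-type liver. Nr0b2 rose 2.65-fold, from 6.59 ± 0.51 to 8.00 ± 0.43 (mean ± SD, n = 6; log2 change 1.41 ± 0.25 SE; limma, Benjamini-Hochberg adjusted p = 0.0244). The Nr0b2 call ended in 9 of 12 fits without a single array and with array weights, only the groups compared, or the letter or replicate number as a block. With the array code number as a block and without wild-type vehicle replicate 6, Nr0b2 stood at 0.70. That setting compares the OCA arrays with vehicle replicate 5 alone. Slc51b rose 2.02-fold, from 4.67 ± 0.22 to 5.68 ± 0.30 (1.02 ± 0.13, adjusted p = 6.99e-04). Cyp8b1, which encodes the enzyme that directs bile acid synthesis towards cholic acid, was 2.44-fold lower, going from 10.87 ± 0.33 to 9.59 ± 0.37 (−1.28 ± 0.14, adjusted p = 3.74e-05). For all 3 genes every OCA array lay beyond every vehicle array. The lowest OCA array for Nr0b2 was 7.31 against a highest vehicle array of 7.30, and for Slc51b 5.23 against 4.96. For Cyp8b1 the highest OCA array was 10.05 against a lowest vehicle array of 10.62. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at −0.67 ± 0.35 (adjusted p = 0.568). The bile salt export pump gene Abcb11 stood at 0.18 ± 0.12 (adjusted p = 0.691), and Nr1h4 itself at −0.07 (adjusted p = 0.815).

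**Figure D1:**
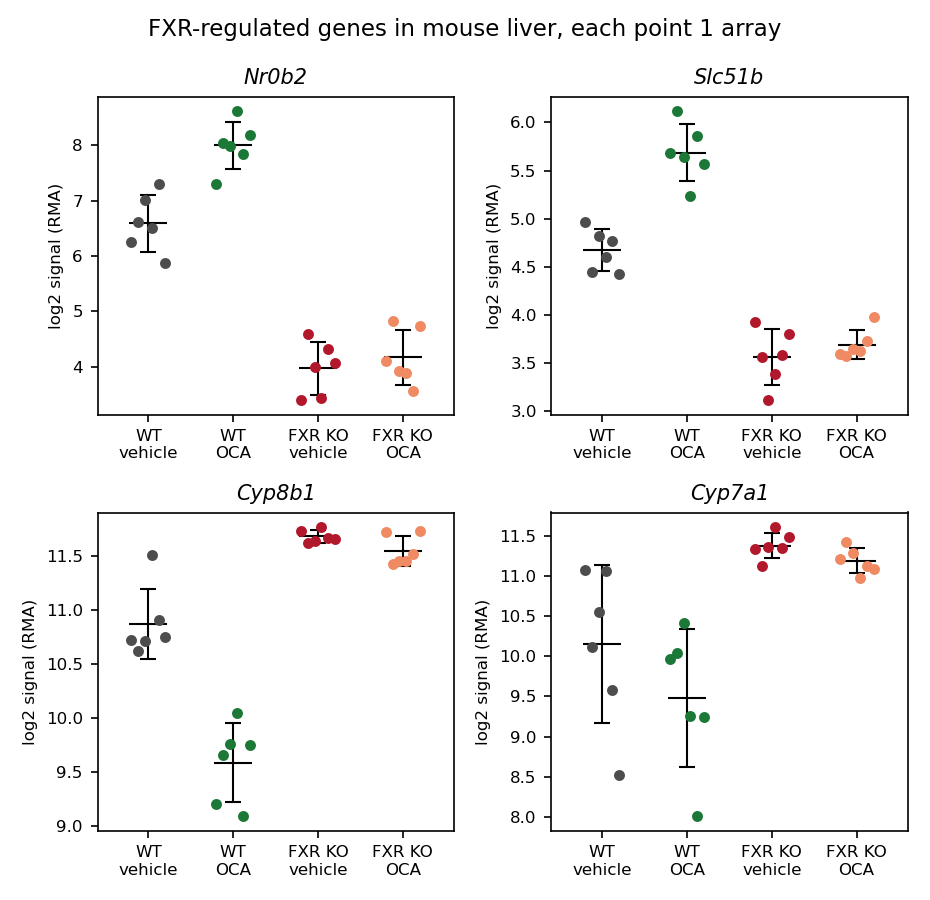
Nr0b2, Slc51b, Cyp8b1 and Cyp7a1 in wild-type and FXR-knockout liver with vehicle or OCA. Each point is 1 array, and bars give the mean ± SD of 6 arrays (log2).

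In all, 13 of 18820 genes were called for OCA in wild-type liver (limma, Benjamini-Hochberg adjusted p < 0.05), 6 higher and 7 lower. Only Nr0b2, Slc51b and Cyp8b1 changed by more than 2-fold. The other higher genes were the zinc finger gene Zfp983 (0.79 ± 0.13, adjusted p = 0.0204), the branching glycosyltransferase gene Gcnt2 (0.54 ± 0.10, adjusted p = 0.0244), the collagen prolyl hydroxylase gene P4ha1 (0.48 ± 0.09, adjusted p = 0.033) and the interferon regulatory factor gene Irf2 (0.34 ± 0.06, adjusted p = 0.033). Lower were Csad, which makes the taurine used to conjugate bile acids (−0.83 ± 0.16, adjusted p = 0.0361), and the choline phosphodiesterase gene Enpp6 (−0.76 ± 0.13, adjusted p = 0.0204). The putative dehydrogenase gene Sccpdh (−0.63 ± 0.12, adjusted p = 0.033) and Arl2bp, a partner of a small GTPase (−0.61 ± 0.11, adjusted p = 0.0244), were lower too. So were Fitm1, which takes part in lipid droplet formation (−0.58 ± 0.11, adjusted p = 0.0411), and the pericyte-enriched signalling regulator Rgs5 (−0.45 ± 0.08, adjusted p = 0.0204). At unadjusted p < 0.05 there were 1782 genes, against 941 expected with no effect.

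The number of wild-type OCA calls depended on the model, on single arrays and on the layout of the arrays. With array weights 5 genes passed, 3 of the 13 among them, and with only the 2 groups compared 2. Taking the array code letter as a block 2 genes passed, over all probe sets 2, with the replicate number as a block 4 and without the arrays ending in _2 7. Cyp8b1 and Slc51b passed in each of these fits that used named genes, and Nr0b2 in none (array weights 1.30, adjusted p = 0.0805; groups compared 1.41, 0.21; letter block 0.0742; replicate block 1.41, 0.0507; without the _2 arrays 1.28, 0.0859). The array codes end in 5, 7 or 9, all OCA arrays of wild-type mice carry number 5 together with vehicle replicates 5 and 6, and vehicle replicates 1 to 4 carry number 7. With that number as a block 667 genes were called (336 higher, 331 lower), 12 of the 13 among them, and within number 5 alone 5 genes. With the block but without wild-type vehicle replicate 6, the OCA arrays were compared with vehicle replicate 5 alone. Cyp8b1 stood at −1.24 with the block (adjusted p = 0.00268), −1.24 within number 5 (0.155) and −1.32 with the block without replicate 6. Slc51b stood at 1.09 (0.00369), 1.09 (0.155) and 0.92, and Nr0b2 at 1.42 (0.0378), 1.42 (0.244) and 0.70. Cyp7a1 changed sign, to 0.44 with the block and within number 5, and stood at −0.10 with the block and without replicate 6. For Cyp7a1 the vehicle arrays of number 5 read 9.58 (replicate 5) and 8.52 (replicate 6), against 10.12 to 11.08 in vehicle replicates 1 to 4. The positive sign thus rests on the 2 lowest vehicle arrays, among them replicate 6, which stands apart from its group. Leaving out single arrays gave 2 genes without OCA replicate 5, 3 without OCA replicate 2 and 5 without OCA replicate 3. It gave 7 without vehicle replicate 2, 7 without vehicle replicate 4 and 21 without vehicle replicate 5. Cyp8b1 (at most 2.15e-04) and Slc51b (at most 0.004) kept their calls in all 12 such fits, whereas Nr0b2 lost its call in 9 of them, with changes of 1.26 to 1.44 there and adjusted p up to 0.0671. Of the other called genes Csad lost its call in 10 of the 12 fits, Fitm1 and Sccpdh in 9, Irf2 and P4ha1 in 8, Arl2bp in 6, Gcnt2 in 5, Zfp983 in 3, Rgs5 in 2 and Enpp6 in 1, with the sign kept and adjusted p at most 0.117.

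None of the 34 gene lists fixed before the data were examined passed for OCA in wild-type liver (camera with an estimated correlation, smallest adjusted p = 0.425), and 8 passed with a preset correlation of 0.01. Of 18 induced FXR targets 2 rose, Nr0b2 and Slc51b, and 2 when adjusted over the list alone. Without wild-type vehicle replicate 6, 1 was called higher, with the number block 2 higher and 1 lower, and within number 5 alone 0. The list's median was 0.02 (adjusted p = 0.425 with an estimated correlation, 0.0499 preset), with the exporter subunit gene Slc51a at −0.23 ± 0.09 (adjusted p = 0.385), against the list's name, and the growth inhibitor gene Osgin1 at 0.61 ± 0.26 (adjusted p = 0.443). Of 16 genes of bile acid synthesis 1 fell, Cyp8b1, and 1 when adjusted over the list alone (adjusted p = 0.425 with an estimated correlation, 0.00877 preset). Its further members Hsd3b7 and Hsd17b4, a sterol dehydrogenase and a peroxisomal enzyme, stood at −0.26 ± 0.10 (adjusted p = 0.369) and −0.11 ± 0.06 (adjusted p = 0.564). Of 17 bile acid and organic ion transporters 1 rose, Slc51b, and 3 passed when adjusted over the list alone (adjusted p = 0.563 with an estimated correlation). The efflux pump genes Abcg2 (−0.29 ± 0.09, adjusted p = 0.207) and Abcb1a (0.53 ± 0.18, adjusted p = 0.306) were the other 2.

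No gene of lipid synthesis passed over all genes with OCA in wild-type liver, and neither list did. Of 20 genes of cholesterol synthesis and uptake 0 passed over all genes and 4 when adjusted over the list alone: the sterol enzyme genes Sqle (0.67 ± 0.16, adjusted p = 0.117), Cyp51 (0.33 ± 0.10, adjusted p = 0.219), Pmvk (0.51 ± 0.17, adjusted p = 0.27) and Lss (0.36 ± 0.13, adjusted p = 0.313). The list's median was 0.28 (adjusted p = 0.425 with an estimated correlation, 4.04e-09 preset), 0.17 without wild-type vehicle replicate 6 and 0.44 with the number block, where 3 members were called higher. In that vehicle array the same list lay at a median of −0.40 from the other 5. Of 18 genes of fatty acid and triglyceride synthesis 0 passed over all genes and 2 when adjusted over the list alone, the carboxylase gene Acaca (0.40 ± 0.11, adjusted p = 0.157) and the citrate lyase gene Acly (0.50 ± 0.16, adjusted p = 0.264). The synthase gene Fasn stood at 0.56 ± 0.20 (adjusted p = 0.336) and the elongase gene Elovl6 at 0.39 ± 0.15 (adjusted p = 0.379). That list's median was 0.16 (adjusted p = 0.425 with an estimated correlation, 6.84e-05 preset), 0.08 without replicate 6 and 0.32 with the block, where 3 members were called higher, and replicate 6 lay at −0.36. Of 22 genes of fatty acid oxidation 0 passed over all genes and 3 when adjusted over the list alone, the fatty acid hydroxylase genes Cyp4a31 (−0.78 ± 0.22, adjusted p = 0.197) and Cyp4a14 (−1.45 ± 0.47, adjusted p = 0.259) and the fatty acid uptake gene Cd36 (−0.42 ± 0.14, adjusted p = 0.291), picked after their values were seen (median −0.15, adjusted p = 0.445 with an estimated correlation, 1.15e-04 preset).

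Marker lists of liver cell types and of plasma proteins gave no call with OCA in wild-type liver, although the number block called 2 Kupffer markers and 2 of 4 adipocyte markers lower and number 5 alone 1 adipocyte marker lower. That block also called clock genes (3 higher, 2 lower) and 1 or 2 members of the glucose, interferon, cell cycle, inflammatory, endoplasmic reticulum stress and fatty acid oxidation lists. Of 12 Kupffer cell markers 0 passed (median −0.26, adjusted p = 0.563 with an estimated correlation, 0.00456 preset), and their median was −0.13 without wild-type vehicle replicate 6 and −0.77 both with the number block and within number 5. In that vehicle array the Kupffer list lay 0.77 above the other 5. Of 9 sinusoidal endothelial markers 0 passed over all genes and 2 when adjusted over the list alone, the Fc receptor gene Fcgr2b (−0.28 ± 0.09, adjusted p = 0.232) and the growth factor receptor gene Kdr (−0.28 ± 0.09, adjusted p = 0.266), picked after their values were seen (median −0.28, −0.07 without replicate 6, adjusted p = 0.425 with an estimated correlation, 5.35e-04 preset). Of 24 complement and coagulation genes 0 passed (median 0.04, adjusted p = 0.51 with an estimated correlation, 0.00877 preset). The 24 acute phase genes had 0 calls and a median of 0.09, which was 0.21 without replicate 6 and −0.28 with the block, and replicate 6 itself lay at a median of 0.99 on that list.

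None of the 13 genes called for OCA in wild-type liver was called in knockout liver, which does not show that they were unchanged there. Nr0b2 stood at 0.20 ± 0.25 (3.97 ± 0.48 with vehicle, 4.17 ± 0.50 with OCA, mean ± SD, n = 6; limma, Benjamini-Hochberg adjusted p = 0.997). Slc51b stood at 0.13 ± 0.13 (adjusted p = 0.996) and Cyp8b1 at −0.13 ± 0.14 (adjusted p = 0.997). Cyp7a1 (−0.19 ± 0.35, adjusted p = 0.997) and Abcb11 (0.20 ± 0.12, adjusted p = 0.985) did not pass either. The other 10 genes had adjusted p of at least 0.977. Csad stood at 0.11 ± 0.16, Enpp6 at 0.23 ± 0.13, Sccpdh at 0.24 ± 0.12, Arl2bp at −0.12 ± 0.11 and Fitm1 at 0.04 ± 0.11. Rgs5 stood at −0.05 ± 0.08, Gcnt2 at −0.09 ± 0.10, Zfp983 at 0.10 ± 0.13, P4ha1 at 0.18 ± 0.09 and Irf2 at 0.05 ± 0.06. Unadjusted p was 0.0526 for P4ha1 and 0.054 for Sccpdh.

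Only 3 genes were called for OCA in knockout liver (limma, Benjamini-Hochberg adjusted p < 0.05). Mogat2, which makes diacylglycerol from monoacylglycerol, fell by 0.90 ± 0.13, from 6.54 to 5.64 (adjusted p = 0.0119). The fatty acyl-CoA reductase gene Far2 fell by 0.47 ± 0.07 (adjusted p = 0.0132) and the transducin subunit gene Gngt1 rose by 0.41 ± 0.07 (adjusted p = 0.0161), with group means of 2.61 to 3.08 and 3.57 to 3.97, near the lower end of the scale. At unadjusted p < 0.05 there were 968 genes, close to the 941 expected with no effect. All knockout OCA arrays carry number 9, as do knockout vehicle replicates 1 and 2, while vehicle replicates 3 to 6 carry number 7. With the array code number as a block and within number 9 alone the count was 0. Both compare the OCA arrays with those 2 vehicle arrays. Leaving out wild-type vehicle replicate 6 with the block keeps the same estimates, and the count was again 0. With no block, the count was also 0 without knockout vehicle replicate 2 and without knockout OCA replicate 6, and 4 at most, without knockout vehicle replicate 4. Gngt1 lost its call in 7 of 12 such fits, and Mogat2 and Far2 in 2 each. Without vehicle replicate 2 the values were 0.38 (0.083), −0.87 (0.0549) and −0.42 (0.0549), and without OCA replicate 6 they were 0.39 (0.0726), −0.87 (0.0599) and −0.43 (0.0648). Gngt1 also lost it without OCA replicates 3 (0.37, 0.0616), 4 (0.39, 0.0714) and 5 (0.40, 0.0594) and without vehicle replicates 5 (0.41, 0.0515) and 6 (0.41, 0.0527).

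No gene list passed for OCA in knockout liver (camera, smallest adjusted p = 0.774 with an estimated correlation), and 4 passed with the preset correlation. These were endoplasmic reticulum stress (median 0.19, adjusted p = 0.774 with an estimated correlation, 0.00701 preset) and fatty acid oxidation (−0.07, adjusted p = 0.818 with an estimated correlation, 0.022 preset). The others were male-biased liver genes (−0.15, adjusted p = 0.774 with an estimated correlation, 0.0258 preset) and sinusoidal endothelial markers (0.12, adjusted p = 0.774 with an estimated correlation, 0.00955 preset). Over all genes 0 members of these lists passed, and 4 male-biased genes, picked after their values were seen, passed when adjusted over the list alone. These were the cytochrome genes Cyp2d9 (−0.48 ± 0.14, adjusted p = 0.763), Cyp4a12a (−0.85 ± 0.31, adjusted p = 0.871) and Cyp4a12b (−0.82 ± 0.31, adjusted p = 0.891) and the urinary protein gene Mup20 (−0.37 ± 0.14, adjusted p = 0.9).

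The difference of the OCA effect between genotypes did not pass for any gene when adjusted over all genes. Cyp8b1 differed by −1.16 ± 0.20 (limma, Benjamini-Hochberg adjusted p = 0.0841, n = 6 per group), Enpp6 by −0.99 ± 0.19 (adjusted p = 0.095), Far2 by 0.56 ± 0.11 (adjusted p = 0.095) and Sccpdh by −0.87 ± 0.17 (adjusted p = 0.0975). Slc51b differed by 0.89 ± 0.19 (adjusted p = 0.168), Gcnt2 by 0.63 ± 0.14 (adjusted p = 0.168) and Nr0b2 by 1.21 ± 0.36 (adjusted p = 0.495). In limma 0 genes passed, 1140 had unadjusted p < 0.05 against 941 expected, and 0 of 34 lists passed (camera, smallest adjusted p = 0.266 with an estimated correlation), against 9 with the preset correlation. Adjusted over the list alone, 2 of the FXR targets passed, Slc51b and Nr0b2, and 1 gene of bile acid synthesis, Cyp8b1. Other settings gave 2 genes with array weights and 34 with the array code number as a block (22 higher, 12 lower). Leaving out single arrays gave 3 genes without wild-type vehicle replicate 2, without wild-type vehicle replicate 6 or without knockout OCA replicate 4. It gave 1 gene without wild-type OCA replicate 3, wild-type OCA replicate 4 or wild-type vehicle replicate 4. Cyp8b1 passed with array weights (−1.17, adjusted p = 0.0253) and without wild-type vehicle replicates 2 (−1.21, 0.033), 4 (−1.03, 0.0469) and 6 (−1.18, 0.0396), wild-type OCA replicate 4 (−1.25, 0.013) or knockout OCA replicate 4 (−1.17, 0.0495). Enpp6 passed with the block (−1.33, adjusted p = 0.0122) and without wild-type vehicle replicate 2 (−1.08) or knockout OCA replicate 4 (−1.05). With the block and without wild-type vehicle replicate 6, Enpp6 stood at −1.34. That setting leaves vehicle replicate 5 alone beside the wild-type OCA arrays. Adjusted over all genes, the OCA effects called in wild-type liver and not in knockout liver were therefore not shown to differ between the genotypes in the fit chosen in advance. The always named Cyp8b1, Slc51b and Nr0b2 had unadjusted limma p of 4.47e-06, 9.09e-05 and 0.00255 and passed over their lists alone.

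Knockout livers lost male-biased and gained female-biased transcripts under vehicle, although all mice were male per the labels. Elovl3, a fatty acid elongase gene of male liver, was 179-fold lower (10.89 ± 0.76 in wild-type, 3.40 ± 0.36 in knockout, mean ± SD, n = 6; log2 change −7.48 ± 0.29 SE; limma, Benjamini-Hochberg adjusted p = 6.01e-16). The steroid dehydrogenase gene Hsd3b5 was 135-fold lower (−7.08 ± 0.30, adjusted p = 2.94e-15) and the organic anion uptake gene Slco1a1 was 84.4-fold lower (−6.40 ± 0.25, adjusted p = 7.42e-16). Among female-biased cytochrome genes Cyp2b9 rose 169-fold (4.48 ± 0.78 to 11.88 ± 0.08, 7.40 ± 0.38, adjusted p = 8.66e-14) and Cyp2b13 rose 152-fold (7.25 ± 0.17, adjusted p = 3.45e-20). All 11 measured male-biased genes fell, 11 when adjusted over the list alone, with Cyp2d9 at −3.01 ± 0.14 and a list median of −1.90 (camera adjusted p = 0.00994 with an estimated correlation). Of 9 female-biased genes 7 rose and 0 fell, 7 when adjusted over the list alone, with the steroid-metabolizing cytochrome gene Cyp3a44 at 1.00 ± 0.11, the peroxisomal transporter gene Abcd2 at 2.36 ± 0.38 and a list median of 1.12 (adjusted p = 0.00724 with an estimated correlation). With the array code number as a block the camera values were 0.0185 and 0.00971, and within number 7 alone the medians were −1.97 (11 of 11 lower) and 1.49 (9 of 9 higher).

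**Figure D2:**
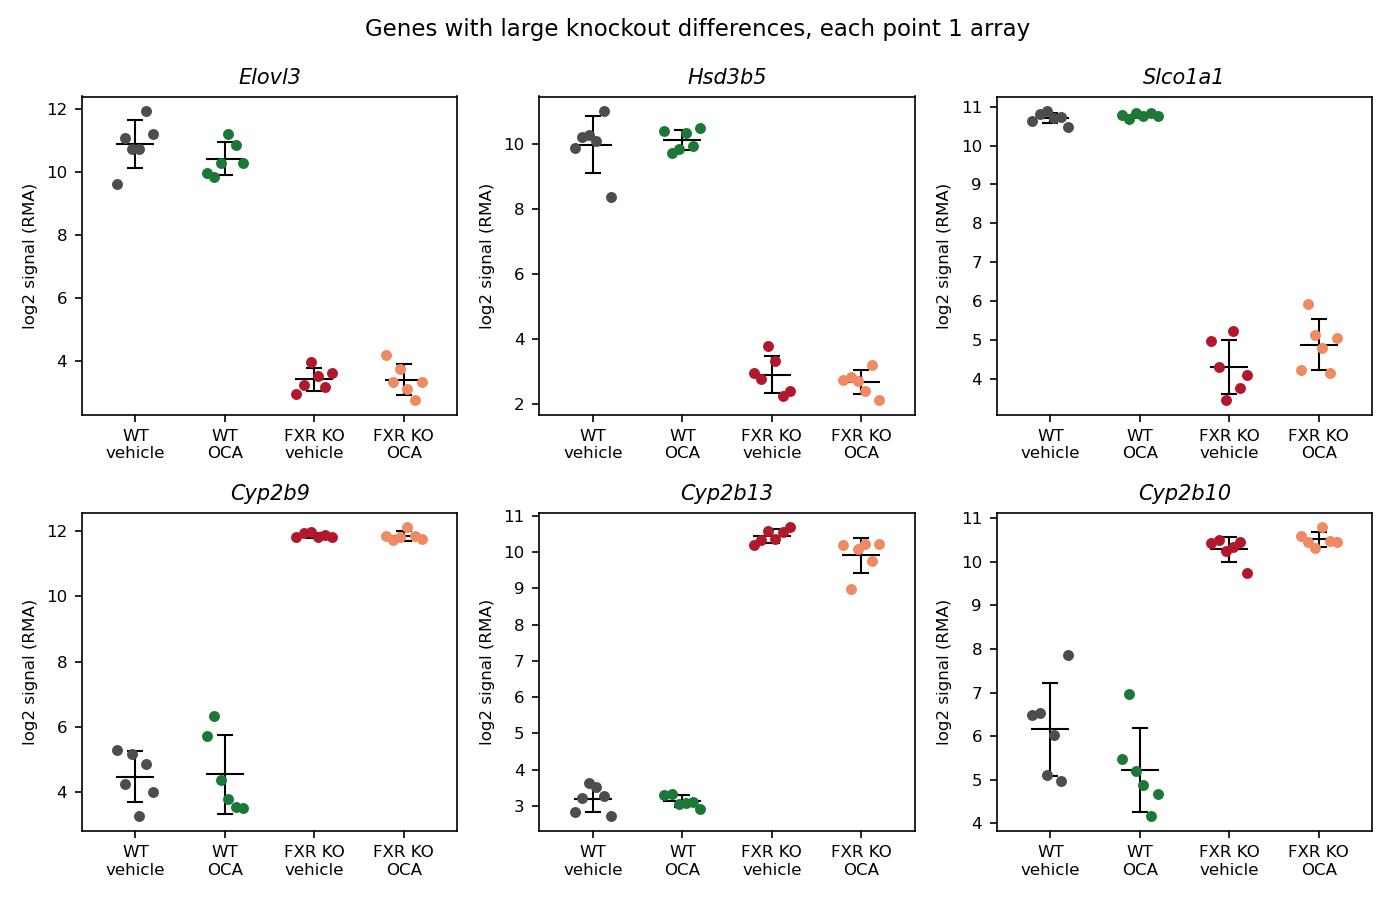
Elovl3, Hsd3b5, Slco1a1, Cyp2b9, Cyp2b13 and Cyp2b10 in each array of the 4 groups. Bars give the mean ± SD of 6 arrays (log2).

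Across the transcriptome 5174 of 18820 genes (27.5%) were called between knockout and wild-type vehicle liver (limma, Benjamini-Hochberg adjusted p < 0.05). Of these 2903 were higher and 2271 lower, and 554 differed by over 2-fold (384 higher, 170 lower). At unadjusted p < 0.05 there were 7061 genes. With the array code number as a block 4281 genes were called, within number 7 alone 4533, with the block and without wild-type vehicle replicate 6 4780, and leaving out single arrays gave 4684 to 5451. The block, with or without that array, and number 7 alone estimate the difference from the same 4 arrays per genotype. The median of all genes was −0.03. Subtracting each array's median over the named genes lowered every knockout difference by 0.17, moved the median of all genes to −0.20 and called 10130 genes, 1776 higher and 8354 lower. On that scale the medians of all 34 lists were lower by the same amount, and 3 of them lost or changed their sign, going from 0.00 to −0.17 (sulfation and glucuronidation), from 0.17 to 0.00 (pericentral hepatocytes) and from 0.05 to −0.12 (neutrophils and monocytes). The changes given here are relative to the deposited scale, on which quantile normalization called 5075 genes and centring on all array rows 5294 (2647 higher, 2647 lower).

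Beyond Cyp2b9 and Cyp2b13, the largest increases in knockout liver ran from 3.93 to 5.33. The cornified envelope gene Sprr1a rose by 5.33 ± 0.21, the cytochrome gene Cyp2a22 by 5.28 ± 0.29, the surface antigen gene Ly6d by 4.99 ± 0.15 and Cyp2c55, an eicosanoid-metabolizing cytochrome gene, by 4.52 ± 0.18 (limma, Benjamini-Hochberg adjusted p at most 2.55e-13, n = 6). The macrophage elastase gene Mmp12 rose from 4.00 to 8.58 (4.58 ± 0.17, adjusted p = 2.14e-16) and the phenobarbital-inducible Cyp2b10 rose 17.5-fold, from 6.16 ± 1.06 to 10.29 ± 0.28 (4.13 ± 0.39, adjusted p = 6.94e-09). The orphan receptor gene Gprc5b rose by 3.96 ± 0.10 and the lysosomal regulator Elapor1 by 3.93 ± 0.14. Among the largest decreases, the serpin pseudogene Serpina4-ps1 fell by 7.39 ± 0.35, the adhesion receptor gene Adgrf1 by 4.26 ± 0.18 and the sulfotransferase gene Sult5a1 by 3.66 ± 0.15. The organic anion transporter gene Slc22a7 fell by 3.59 ± 0.24, the urinary protein gene Mup21 by 3.38 ± 0.24, the oxysterol hydroxylase gene Cyp7b1 by 3.29 ± 0.26 and the carboxylesterase gene Ces3b by 3.16 ± 0.20.

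Knockout livers held less Nr0b2, Abcb11 and Slc51b, which FXR induces, and more Cyp8b1 and Cyp7a1, which it represses. Nr0b2 was 6.16-fold lower (−2.62 ± 0.25; limma, Benjamini-Hochberg adjusted p = 1.21e-08, n = 6), Abcb11 3.20-fold lower (−1.68 ± 0.12, adjusted p = 3.79e-11) and Slc51b 2.16-fold lower (−1.11 ± 0.13, adjusted p = 4.73e-07). Cyp8b1 rose 1.75-fold (0.81 ± 0.14, adjusted p = 6.81e-05) and Cyp7a1 2.34-fold, from 10.15 ± 0.98 to 11.38 ± 0.16 (1.23 ± 0.35, adjusted p = 0.0091). The Cyp7a1 call ended with the array code number as a block (0.75, adjusted p = 0.122), where the difference is estimated from the number 7 arrays. Wild-type vehicle replicate 6 carries number 5 and does not enter that estimate (0.75, adjusted p = 0.103 without it). In that array Cyp7a1 lay at −1.96 from the other 5. With no block the call held in all 12 fits without a single array (adjusted p at most 0.0244). Of 18 FXR targets 8 fell and 3 rose, 11 when adjusted over the list alone (median −0.18, adjusted p = 0.171 with an estimated correlation, 0.0316 preset). Against the list's name, the lipoprotein receptor gene Vldlr rose by 2.62 ± 0.17, and the heparan sulfate proteoglycan gene Sdc1 and the canalicular exporter gene Abcc2, picked here after their values were seen, rose by 0.57 and 0.52. Of 16 genes of bile acid synthesis 8 fell and 4 rose, 12 when adjusted over the list alone (median −0.22, adjusted p = 0.0789 with an estimated correlation, 0.00583 preset). The lowest p belonged to the hydroxylase genes Cyp7b1 (−3.29 ± 0.26), Cyp39a1 (−1.46 ± 0.15) and Cyp2c70 (−1.04 ± 0.11) and the racemase gene Amacr (−0.65 ± 0.07). Besides Cyp8b1 and Cyp7a1, the reductase gene Akr1d1 (0.42 ± 0.11) and Hsd17b4 (0.16 ± 0.06, adjusted p = 0.0371), picked after their values were seen, rose. Hsd17b4 lost its call in 8 of 12 fits without a single array (0.13 to 0.16 there, adjusted p up to 0.0996), with the block (0.16, adjusted p = 0.105) and, at −0.01, after centring on the named genes. Of 17 transporters 5 rose and 7 fell, 14 when adjusted over the list alone (median −0.14, adjusted p = 0.679 with an estimated correlation), among them the basolateral bile acid exporter gene Abcc4, higher by 3.52 ± 0.13.

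Stellate cell and matrix genes rose together with antioxidant genes in knockout liver. Of 17 fibrosis and stellate cell genes 16 rose and 0 fell, 16 when adjusted over the list alone (median 1.07, camera adjusted p = 0.00561 with an estimated correlation). The proteoglycan gene Lum rose by 1.55 ± 0.10, the protease inhibitor gene Timp2 by 1.25 ± 0.10, and the collagen genes Col1a1 and Col1a2 by 1.54 ± 0.15 and 1.25 ± 0.12 (limma, Benjamini-Hochberg adjusted p at most 1.26e-08, n = 6). Of 16 glutathione and antioxidant genes 13 rose and 1 fell, 15 when adjusted over the list alone (median 0.71, adjusted p = 0.00561 with an estimated correlation). The glutathione transferase genes Gstm2 (1.56 ± 0.08) and Gstm3 (1.68 ± 0.11), the sulfiredoxin gene Srxn1 (1.57 ± 0.10) and the epoxide hydrolase gene Ephx1 (0.78 ± 0.06) led this list, and Gstp1, picked after its value was seen, fell by 0.37. With the array code number as a block camera gave 0.00594 for each of these lists, and within number 7 their medians were 1.08 (15 higher) and 0.73 (12 higher, 1 lower). The list of cytochrome P450s of drug metabolism held 20 genes, which include the receptor gene Nr1i2. Of these 10 rose and 2 fell, 13 when adjusted over the list alone, led by Cyp2b13, Cyp2c55, Cyp2b9 and Cyp2b10 (median 0.43, adjusted p = 0.0624 with an estimated correlation, 2.31e-06 preset). The 2 that fell, picked after their values were seen, were Cyp2c37 (−0.86 ± 0.14) and the xenobiotic receptor gene Nr1i2 (−0.29 ± 0.08).

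Of 22 cell cycle genes 17 rose and 0 fell in knockout liver, 17 when adjusted over the list alone (median 0.63, camera adjusted p = 0.0913 with an estimated correlation, 8.02e-08 preset). The replication licensing genes Mcm2 (1.57 ± 0.11), Mcm6 (1.27 ± 0.15) and Mcm4 (0.64 ± 0.12) rose, as did the cyclin gene Ccnd1 (1.62 ± 0.18; limma, Benjamini-Hochberg adjusted p at most 1.6e-04, n = 6). Of 20 inflammatory mediators 8 rose and 1 fell, 10 when adjusted over the list alone (median 0.39, adjusted p = 0.339 with an estimated correlation, 0.00756 preset). These included the chemokine genes Ccl3 (1.42 ± 0.19) and Cxcl10 (1.13 ± 0.20), the adhesion molecule gene Vcam1 (1.37 ± 0.23) and the NF-κB inhibitor gene Tnfaip3 (0.72 ± 0.13). The cytokine gene Il6, picked after its value was seen, fell by 0.25 ± 0.09 (adjusted p = 0.0301), and lost its call in 6 of 12 fits without a single array (adjusted p up to 0.0774) and with the number block (adjusted p = 0.115). Without wild-type vehicle replicate 6, in which this list lay 0.26 above the other 5, 10 rose and 0 fell.

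Among the metabolic lists of knockout liver, amino acid and ammonia metabolism passed, though not under every setting. Of 21 genes of amino acid and ammonia metabolism 18 fell and 1 rose, 19 when adjusted over the list alone (median −0.36, camera adjusted p = 0.0423 with an estimated correlation). The histidine-degrading enzyme genes Hal (−1.53 ± 0.13) and Uroc1 (−0.59 ± 0.07) and the urea cycle gene Otc (−0.41 ± 0.05) fell. The glyoxylate enzyme gene Agxt fell by 1.00 ± 0.09, and Oat, an ornithine-degrading enzyme gene picked after its value was seen, rose by 0.34, or 0.25 with the array code number as a block (adjusted p = 0.054). This list did not pass with that block (adjusted p = 0.0877) or without wild-type vehicle replicate 6 (adjusted p = 0.0736), although 18 genes still fell without that array, and within number 7 its median was −0.38 (15 lower, 1 higher). Of 15 genes of glucose metabolism 8 fell and 0 rose, 8 when adjusted over the list alone (median −0.34, adjusted p = 0.0624 with an estimated correlation, 0.0053 preset). That median was −0.23 without wild-type vehicle replicate 6 and −0.19 with the number block or within number 7. The gluconeogenic genes Pck1 (−1.23 ± 0.13) and G6pc (−1.34 ± 0.21) and the glycogen enzyme genes Gys2 (−0.70 ± 0.11) and Pygl (−0.42 ± 0.06) fell (limma, Benjamini-Hochberg adjusted p at most 1.59e-05, n = 6).

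Lipid genes moved in various directions in knockout liver, and none of their lists passed. Of 20 cholesterol genes 11 rose and 1 fell, 13 when adjusted over the list alone (median 0.28, camera adjusted p = 0.475 with an estimated correlation, 0.00333 preset), with the sterol enzyme genes Hmgcs1 (1.18 ± 0.16), Mvd (1.35 ± 0.26), Fdft1 (0.82 ± 0.13) and Dhcr7 (0.64 ± 0.09) higher and Ebp, picked after its value was seen, lower (−0.28 ± 0.06). Without wild-type vehicle replicate 6, in which this list lay at −0.40, 9 rose, 2 fell and the median was 0.21. Of 18 fatty acid synthesis genes 7 rose and 3 fell, 12 when adjusted over the list alone (median 0.21, adjusted p = 0.522 with an estimated correlation, 0.0262 preset). The malic enzyme gene Me1 (0.74 ± 0.12), Elovl6 (0.80 ± 0.15) and Fasn (0.94 ± 0.20) rose and the lipogenic regulator Thrsp fell by 1.00 ± 0.22. The transcription factor genes Mlxipl (−0.42 ± 0.12) and Srebf1 (−0.66 ± 0.24, adjusted p = 0.0384), picked after their values were seen, also fell, Srebf1 losing its call in 7 of 12 fits without a single array (−0.67 to −0.53 there, adjusted p up to 0.105). Without replicate 6, at −0.36 on this list, the list's median was 0.14. Of 22 genes of fatty acid oxidation and PPARα targets 10 rose and 2 fell, 14 when adjusted over the list alone (median 0.23, adjusted p = 0.39 with an estimated correlation, 0.00278 preset). The fatty acid uptake gene Cd36 (2.49 ± 0.14), the pantetheinase gene Vnn1 (1.90 ± 0.20), the thioesterase gene Acot2 (1.92 ± 0.21) and the pyruvate dehydrogenase kinase gene Pdk4 (2.37 ± 0.30) rose (limma, Benjamini-Hochberg adjusted p at most 1.07e-06, n = 6). The lipid carrier gene Fabp1 (−0.22 ± 0.07) and the carnitine transferase gene Cpt1a (−0.25 ± 0.08), picked after their values were seen, fell. The Fabp1 call ended with quantile normalization (−0.18, adjusted p = 0.078) and with the array code letter as a block (−0.18, 0.0855), and the Cpt1a call with only the groups compared (−0.25, 0.0781), with the letter block (−0.24, 0.0632) and without knockout vehicle replicate 2 (−0.23, 0.0521) or wild-type vehicle replicate 4 (−0.19, 0.068). Of 20 lipoprotein genes 5 rose and 6 fell, 14 when adjusted over the list alone, with a median of −0.04, a mean of 0.13 and a downward test direction (adjusted p = 0.709 with an estimated correlation). Vldlr (2.62 ± 0.17) and the lipid export gene Tm6sf2 (0.67 ± 0.10) rose, and the triglyceride regulator Apoa5 (−0.81 ± 0.08) and the HDL receptor gene Scarb1 (−0.41 ± 0.07) fell.

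**Figure D3:**
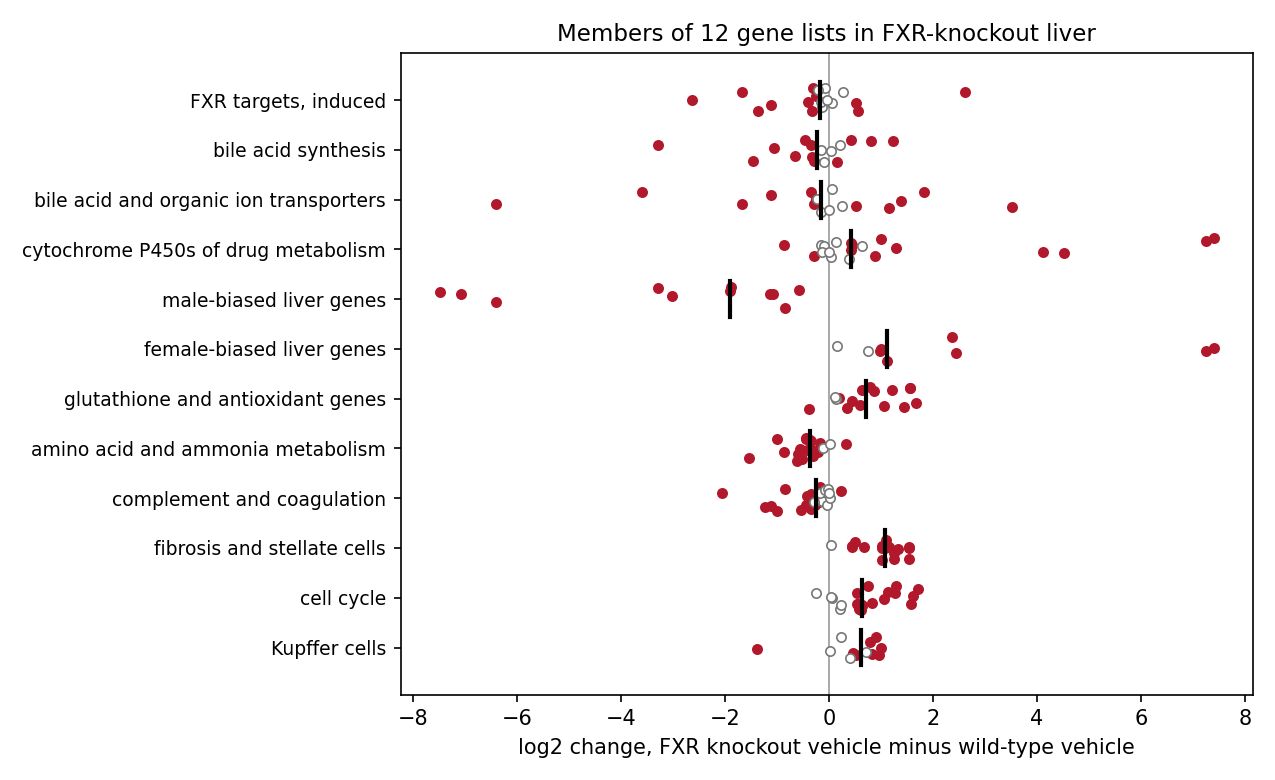
Knockout differences of the members of 12 gene lists. Each point is 1 gene, filled where the Benjamini-Hochberg adjusted p was under 0.05, and the bar marks the list median.

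Of the 13 genes called for OCA in wild-type liver, 9 were also called for knockout against wild type under vehicle, with the opposite sign. Nr0b2, Slc51b, Gcnt2 and Irf2 were higher with OCA and lower in knockout, and Cyp8b1, Csad, Sccpdh, Arl2bp and Fitm1 lower with OCA and higher in knockout. P4ha1 was higher and Enpp6 lower in both comparisons. The Enpp6 knockout call ended with the array code number as a block (−0.32, adjusted p = 0.0636) and within number 7 (−0.32, 0.086). It also ended with the block and without wild-type vehicle replicate 6 (−0.32, 0.0645). These settings all estimate the knockout difference from the same number 7 arrays. Not called in knockout were Zfp983 (−0.21, adjusted p = 0.259) and Rgs5 (0.16, adjusted p = 0.122). Independent lists of these sizes would share 1.80 genes moving opposite ways and 1.77 moving the same way. In simulations of unchanged groups, where all arrays were simulated and both comparisons used the same simulated vehicle arrays, the number shared was 0. That value sets no bar, because unchanged groups need not hold any calls to share. Both comparisons use the wild-type vehicle arrays. Across genes, which are not independent replicates, the changes correlated at 0.05 against 0.5 in the simulation. The 2 correlations cannot be compared, because the real knockout differences widen the spread of changes and the simulation holds none. The covariance was 0.00276 against 0.00644, a difference of −0.00368. The simulation gave all groups 1 spread per gene, whereas the median gene SD was 0.176 in wild-type and 0.13 in knockout vehicle liver. That difference in covariance is therefore only rough. With the vehicle arrays split 3 and 3 in all 20 ways, 5 to 79 genes were called for OCA. Of these 3 to 37 (median 7) moved opposite ways and 0 to 13 the same way. In these splits the mean correlation was −0.094 (−0.185 to −0.014) and the mean covariance −0.00684. With the array code number as a block 667 genes were called for OCA, of which 226 moved opposite ways and 41 the same way. The overlap of independent lists was not computed for that setting, so these larger counts do not show a stronger overlap. With no block and without wild-type vehicle replicate 6 there were 6 opposite.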

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

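The tests of noise and of a sample swap in wild-type vehicle replicate 6, and of that array's part in the number block, were chosen only after the result was seen.

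Wild-type vehicle replicate 6 lay above the other 5 arrays of its group on acute phase genes (median 0.99, with Saa2 at 5.23 and Lcn2 at 4.92), neutrophil and monocyte markers (0.93), Kupffer markers (0.77) and endoplasmic reticulum stress genes (0.43), and below them on cholesterol synthesis (−0.40). Random measurement noise on this array was argued against by the acute phase median of 0.99, at percentile 100 of 10000 random lists of equal size and level. A swap with an OCA-treated wild-type array was argued against by Slc51b at 4.42, below the OCA range of 5.23 to 6.12, and by Cyp8b1 at 10.75, above the OCA range of 9.09 to 10.05. Neutrophils and other blood cells in this liver sample stayed open, since their list's median of 0.93 lay close to the acute phase median of 0.99 without exceeding it. Of their markers S100a8 lay 2.23, S100a9 1.16, Itgam 0.93 and Csf3r 0.72 higher, and Lyz2 only 0.27. An inflamed or stressed animal, or sample handling, may also give this pattern and was not tested.

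With the array code number as a block, 13 genes called for OCA in wild-type liver became 667. Part of this may come from 1 unusual vehicle array, wild-type vehicle replicate 6, inside array code number 5: without it the count was 77, of which 38 were shared with the 667, whereas without replicate 5 it was 2767. The blocked comparison rests on those 2 vehicle arrays of number 5, so either carries much weight. Each of the fits without 1 of them compares the OCA arrays with a single vehicle array, so these counts are weak evidence. A shift between array code numbers that acts on all samples was tested on knockout vehicle arrays of numbers 7 and 9, with 0 genes called but 1743 at unadjusted p < 0.05 against 941 expected. With 4 arrays against 2, the bound set for that test was too weak, and such a shift stays open.

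Splitting the same arrays in other ways 100 times, the real split included, gave as many calls as the real one (13) in 4 splits for OCA in wild-type liver, with 87 in the highest other split. The splits with 87, 51 and 20 calls all put wild-type vehicle replicates 4, 5 and 6 with OCA replicates 5 and 6. This was seen only after the splits were ranked, and whether a structure of the samples other than treatment lies behind it was not tested. For OCA in knockout liver 1 of 100 splits reached the real 3 calls (highest other 1), and for knockout against wild type 1 of 100 reached 5174. The highest other knockout split had 2198 calls, placed wild-type vehicle replicate 6 with 5 knockout arrays and so kept most of the genotype difference. For the difference between genotypes the real count was 0, which all 100 splits reach by definition (highest other 2), so the splits carry no information on it.

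Among 39 genes in 4 groups (156 groups) 8 held an array far from the others of its group, where chance alone gives about 1 in 20, and 0 of the 8 involved wild-type vehicle replicate 6. Cyp8b1 read 11.51 in wild-type vehicle replicate 4, next to 10.91. Fitm1 read 10.98 in knockout vehicle replicate 6, next to 11.22. Cyp2b9 read 12.13 in knockout OCA replicate 4, next to 11.86. Mmp12 read 4.51 in wild-type OCA replicate 1, next to 4.09. Cyp2b10 read 9.74 in knockout vehicle replicate 6, next to 10.26. Serpina4-ps1 read 9.27 in wild-type OCA replicate 5, next to 10.58. Slc22a7 read 4.04 in knockout vehicle replicate 2, next to 4.53. Ces3b read 12.10 in wild-type OCA replicate 4, next to 11.73. Of 14338 probe sets without a single symbol 1485 were called for knockout and carry no gene name here.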

How the results depend on the processing

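The number block without wild-type vehicle replicate 6 and centring on the named genes were chosen only after the result was seen, and the cause was not tested for any shift below unless stated.

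OCA in wild-type liver gave 13 calls, and 24 with a mean signal of at least 20, 22 at or above the median gene, 5 with array weights, 2 with only the groups compared, 667 with the number block, 5 within number 5, 2 with the letter block, 7 without the _2 arrays, 2 over all probe sets and 77 with the number block and without wild-type vehicle replicate 6. Leaving out single arrays gave 2 to 21. Of 180 values of the 13 genes under other settings 109 kept the call, 71 lost it and 0 changed sign.

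OCA in knockout liver gave 3 calls, and 1 with a mean signal of at least 20, 0 at or above the median gene, 11 with array weights, 0 with only the groups compared, 0 with the number block, 0 within number 9, 0 with the letter block, 0 without the _2 arrays, 5 over all probe sets and 0 with the number block and without replicate 6. The number block, with or without replicate 6, and number 9 alone share 1 estimate, from 2 vehicle arrays. Leaving out single arrays gave 0 to 4.

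Knockout gave 5174 calls and 10130 after centring on the named genes, whose array medians were 5.19 in wild-type and 5.35 in knockout vehicle liver; whether that gap is biological was not tested. Of 2209 values of 159 named genes under other settings 2135 kept the call and 73 lost it. Lost in at least 1 setting were the knockout calls of Akr1d1, Cpt1a, Cyp7a1, Enpp6, Fabp1, Fabp4, Far2, Fth1, Hsd17b13, Hsd17b4, Il6, Krt19, Mbl2, Muc1, Nfil3, Oasl1, Oat, Oit3, Papss2, Psmb9, Rbp4, Srebf1, Ugt2b36, Utp20 and Vtn. The difference between genotypes gave 0, and 2 with array weights, 34 with the number block, 12 with the number block and without replicate 6 and 0 to 3 without single arrays. With the preset correlation 8, 4, 20 and 9 lists passed for OCA in wild-type liver, OCA in knockout liver, knockout and the difference, against 0, 0, 5 and 0. Opposite changes of OCA and knockout went from 9 of 13 OCA calls to 226 of 667 with the number block.

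The replicate block gave 4 genes for OCA in wild-type liver, 3 for OCA in knockout liver, 5060 for knockout and 0 for the difference. The numbers do not pair the samples: each is a different mouse, deviations of arrays with the same number correlated at −0.08 to 0.17 over 36 pairs, and only 2 arrays matched their own number best.

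Among the named genes, the only ones followed for this, 1 called value changed sign, Hsd17b4 for knockout, from 0.16 to −0.01 after centring on the named genes. For OCA in wild-type liver Nr1h4 (main −0.07) became 0.10 and Abcb11 (0.18) −0.15 with the number block and without replicate 6. That setting leaves vehicle replicate 5 alone beside the OCA arrays. Cyp7a1 (−0.67) became 0.44 with the number block and 0.44 within number 5. Both settings rest on vehicle replicates 5 and 6, which read lower for Cyp7a1 (9.58 and 8.52) than vehicle replicates 1 to 4 (10.12 to 11.08). For OCA in knockout liver, the number block, with or without replicate 6, and number 9 alone gave the same estimates, from 2 vehicle arrays. There Nr1h4 became 0.02, Slc51b −0.05, Irf2 −0.01 and Fitm1 −0.02. Leaving out single arrays moved Fitm1 between −0.01 and 0.09. For the difference Nr1h4 became 0.01 with array weights, 0.08 without the _2 arrays and 0.09 with the number block and without replicate 6, and −0.07 to 0.02 without single arrays. Abcb11 became 0.09 and Cyp7a1 0.48 with the number block, and Abcb11 ranged from −0.13 to 0.04 without single arrays. For knockout the adipocyte gene Adipoq (−0.23) ranged from −0.30 to 0.04.

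Signal over background was not analysed here, as the table holds no background values: a gene near the lower end of the scale cannot be told from an absent one, and its fold changes are compressed.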

Other observations

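The hypotheses on sex-biased genes other than hepatocyte share, and all tests on the region next to Nr1h4 and on macrophages, were chosen only after the result was seen. The prediction on hepatocyte share was written before its result, but its list of major hepatocyte transcripts was chosen after the data were seen.

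In knockout liver, of 24 complement and coagulation genes 15 fell and 1 rose, 18 passing when adjusted over the list alone (median −0.25, camera adjusted p = 0.0698 with an estimated correlation, 3.17e-08 preset): the membrane attack genes C9 (−2.05 ± 0.16), C8b (−1.22 ± 0.12) and C8g (−0.53 ± 0.05) fell and the clotting factor gene F7 fell by 1.00 ± 0.09 (limma, Benjamini-Hochberg adjusted p at most 1.39e-08). The lectin gene Mbl2, picked after its value was seen, rose by 0.24 ± 0.08 (adjusted p = 0.0212), and stood at 0.17 with the number block (0.187). Of 24 acute phase genes 5 rose and 5 fell, 10 when adjusted over the list alone, with a median of −0.03 and a mean of 0.30 (adjusted p = 0.953 with an estimated correlation). The plasma glycoprotein genes Orm2 (3.43 ± 0.44) and Orm3 (2.65 ± 0.42) and the pentraxin gene Apcs (1.26 ± 0.25) rose and the cytokine receptor gene Il6ra fell by 1.22 ± 0.12, and without wild-type vehicle replicate 6, at 0.99 on this list, the median was 0.09. Of 16 endoplasmic reticulum stress genes 10 fell and 2 rose, 13 when adjusted over the list alone (median −0.31, adjusted p = 0.39 with an estimated correlation, 0.0113 preset). The asparagine synthetase gene Asns (2.47 ± 0.22) and Atf3 (1.62 ± 0.20) rose against Herpud1 (−0.48 ± 0.07) and Atf4 (−0.54 ± 0.08), and without replicate 6, at 0.43 on this list, 8 fell and 3 rose. Of 14 iron and heme genes 7 rose and 1 fell, 8 when adjusted over the list alone (median 0.33, adjusted p = 0.0746 with an estimated correlation, 0.00774 preset). The ferritin genes Ftl1 (0.73 ± 0.08) and Fth1 (0.24 ± 0.05), the hepcidin gene Hamp2 (1.78 ± 0.35) and the heme oxygenase gene Hmox1 (1.22 ± 0.24) rose, Fth1 standing at 0.08 (adjusted p = 0.192) after centring on the named genes, and the transferrin receptor gene Tfr2, picked after its value was seen, fell by 0.26 ± 0.06. Of 13 sulfation and glucuronidation genes 4 rose and 4 fell, 9 when adjusted over the list alone (median 0.00, adjusted p = 0.892 with an estimated correlation), with Ugdh (1.55 ± 0.08) and Ugt2b34 (0.63 ± 0.05) higher and Sult2a8 (−2.77 ± 0.16) and Ugt2b1 (−0.93 ± 0.09) lower. Also called, and picked after their values were seen, were Ugt2b35 (0.60 ± 0.09), Papss2 (0.33 ± 0.07), Ugt2b38 (−0.58 ± 0.16) and Ugt2b36 (−0.17 ± 0.06), the last losing its call in 3 of 12 fits without a single array (adjusted p up to 0.0663). Of 16 interferon genes 1 rose, Oasl1 (0.39 ± 0.13), and 3 fell, Psmb8 (−0.67 ± 0.11), Ifit3 (−0.56 ± 0.15) and Psmb9 (−0.30 ± 0.09), 4 when adjusted over the list alone (median −0.06, adjusted p = 0.799 with an estimated correlation). With the number block Psmb9 stood at −0.25 (adjusted p = 0.11) and Oasl1 at 0.22 (0.321), and Oasl1 also lost its call without knockout vehicle replicate 2 (0.37, 0.0528) and without wild-type vehicle replicate 6 (0.30, 0.0755). Of 15 clock genes 2 fell, Cry1 (−0.75 ± 0.17) and Nfil3 (−0.95 ± 0.31), 2 when adjusted over the list alone (median −0.15, adjusted p = 0.39 with an estimated correlation). Nfil3 stood at −0.37 with the number block (adjusted p = 0.398), −0.37 within number 7 (0.152) and −0.88 without knockout vehicle replicate 1 (0.0532).

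In knockout liver none of the following cell type lists passed. Of 7 periportal genes 5 fell and 1 rose, 6 when adjusted over the list alone (median −0.36, camera adjusted p = 0.0624 with an estimated correlation, 0.00151 preset), with Hal, Pck1, Cyp2f2 (−0.36 ± 0.05) and the urea cycle gene Cps1 (−0.30 ± 0.05) lower (limma, Benjamini-Hochberg adjusted p at most 5.33e-05). The lipid droplet gene Hsd17b13, picked after its value was seen, was higher by 0.17 ± 0.05, and by 0.15 with the number block (adjusted p = 0.0812). Of 10 pericentral genes 4 rose and 2 fell, 6 when adjusted over the list alone (median 0.17, adjusted p = 0.669 with an estimated correlation). That median was 0.11 without wild-type vehicle replicate 6 and 0.08 with the number block or within number 7. The ammonia transporter gene Rhbg (1.22 ± 0.14) and Lect2 (0.56 ± 0.07) rose, as did Lgr5 (0.73 ± 0.18) and Oat (0.34 ± 0.08), picked after their values were seen. The glutamate transporter gene Slc1a2 (−0.68 ± 0.08) and the glutamine synthetase gene Glul (−0.43 ± 0.08) fell. Of 12 Kupffer cell markers 7 rose and 1 fell, 9 when adjusted over the list alone (median 0.61, adjusted p = 0.475 with an estimated correlation, 0.00759 preset), with Vsig4 (1.01 ± 0.19), C1qb (0.91 ± 0.19) and Clec4f (0.47 ± 0.09) higher and the scavenger receptor gene Cd163 lower by 1.38 ± 0.19. Without wild-type vehicle replicate 6, at 0.77 on this list, 9 rose, and within number 7 the median was 0.84. Of 9 neutrophil and monocyte markers 2 rose, Lyz2 (0.99 ± 0.25) and Ccr2 (0.62 ± 0.17), 3 when adjusted over the list alone (median 0.05, adjusted p = 0.765 with an estimated correlation), and without replicate 6, at 0.93 on this list, 5 rose and the median was 0.42. Of 6 cholangiocyte markers 3 rose, Epcam (0.58 ± 0.10), Krt19 (0.48 ± 0.13) and Muc1 (0.56 ± 0.17), 3 when adjusted over the list alone (median 0.36, adjusted p = 0.0913 with an estimated correlation, 0.0312 preset), and Krt19 stood at 0.38 within number 7 (adjusted p = 0.208) and 0.38 with the number block (0.085), and Muc1 at 0.45 with the letter block (0.0777). Of 9 sinusoidal endothelial markers 2 fell, Kdr (−0.36 ± 0.09) and Oit3 (−0.40 ± 0.12), 4 when adjusted over the list alone (median −0.13, adjusted p = 0.669 with an estimated correlation), Oit3 losing its call without knockout vehicle replicate 6 (−0.32, 0.0561) and with the number block (−0.39, 0.0632). Of 8 T and NK cell markers 1 fell, Cd4 (−0.59 ± 0.13), 3 when adjusted over the list alone (median −0.15, adjusted p = 0.39 with an estimated correlation), and of 4 B cell markers 0 passed either way (median −0.17, adjusted p = 0.475 with an estimated correlation). Of 2 red blood cell genes the heme synthesis gene Alas2 fell by 1.15 ± 0.11, 1 when adjusted over the list alone (adjusted p = 0.171 with an estimated correlation). Of 4 adipocyte genes the fatty acid carrier gene Fabp4 rose by 0.56 ± 0.20 (adjusted p = 0.0332), 1 when adjusted over the list alone (list adjusted p = 0.868 with an estimated correlation), and lost its call in 6 of 12 fits without a single array (0.45 to 0.54 there, adjusted p up to 0.0962). Of 4 exocrine pancreas genes 0 passed either way (median −0.07, adjusted p = 0.669 with an estimated correlation).

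Male-biased genes were lower and female-biased genes higher in knockout liver, which may have several sources. Female animals among the knockout mice were argued against by Y-linked genes, which differed by a mean of −0.10 (Kdm5d −0.19, Uty −0.01, Eif2s3y −0.10), and by Xist at 0.05. A difference between array code numbers was argued against by the male-biased median of −1.97 within number 7. A lower share of hepatocytes in knockout liver stays open as a contribution: major hepatocyte transcripts had a median of −0.07 but read 12.22 to 13.45 in wild-type vehicle liver, near the top of the scale, where a fall may be compressed, and a lower share alone would not raise the female-biased list (median 1.12). These values met the bound written against a lower share, but that bound took no account of the compression. Loss of FXR activity itself rather than another difference between the 2 lines of mice stays open, since OCA moved the male-biased list of wild-type liver by only −0.03.

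Gas2l3, the gene next to Nr1h4 in the annotation, rose by 2.80 ± 0.19, from 6.01 to 8.81 (limma, Benjamini-Hochberg adjusted p = 1.31e-11), and Utp20 nearby fell by 0.28 (adjusted p = 0.0259; −0.19 with the number block, 0.268). As a hypothesis, a wider changed region around the targeted gene (flanking donor genome) might raise it. Of the 50 nearest measured genes on each side 31% were called, at percentile 69.9 of 16775 windows and within their middle 95% (14 to 39). The window thus held no excess of called genes. With 27.5% of all genes called, such a share cannot show a change in only some neighbours, so flanking donor genome stays open. A local effect of the targeted allele on its neighbour stays open too.

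A list of lipid-associated macrophage genes, chosen after several of its members had been seen, had 17 of 19 genes higher in knockout liver, among them Gpnmb (3.42), Lgals1 (3.24), Atp6v0d2 (3.14), Cd63 (3.00) and Trem2 (1.42). As a hypothesis, knockout liver may hold more macrophages of this state. More macrophages of every kind stay open: the Kupffer median was 0.61 beside 1.24 for this list, 1.04 over 18 genes without Mmp12, and 0.84 beside 1.35 within number 7. Choosing the list after members were seen raises its median, and leaving out Mmp12 and the 5 genes named here, which gave 0.81 over 13 genes, lowers it, so the gap has no unbiased size. Expression of the same genes by other cells stays open too.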
